A study of Mus musculus with 8 samples.

How the data were processed

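Cells of the ascending thoracic aorta of 3 aged wildtype mice, 81, 84 and 88 weeks old per the labels, were measured by single-cell RNA sequencing together with hashtag antibodies, which are barcoded antibodies that mark the cells of one animal each before pooling. Per the labels, tissue was digested for 60 min at 37 °C with collagenase II at 10 mg/mL and elastase at 1 mg/mL, passed through a 70 µm strainer and depleted of dead cells, and about 15000 viable cells were loaded. The 8 deposited samples were 4 gene expression libraries and 4 hashtag libraries of the same cell pool. They are sequencing libraries and not animals, and the deposited values do not keep them apart, so no depth per library could be given. A deposited reference table states that hashtag 1 marks the animal of 81 weeks, hashtag 2 that of 84 weeks and hashtag 3 that of 88 weeks.

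The deposited matrix holds raw UMI counts, not normalised, for 32285 genes and 3 hashtags in 26916 barcodes. UMIs (unique molecular identifiers) count captured molecules, so that PCR copies are counted once. Per the file headers the authors made it with Cell Ranger 6.0.1, and the labels name Cell Ranger, Seurat 4.0.5 and the mm10 genome. The file stops at a minimum of 900 UMIs per barcode. A cell annotation of the authors was not used here, so classes were rebuilt here and can differ from those of the study.

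Hashtags were called on all barcodes with HTODemux of Seurat 5.3.0 (centred log ratios, quantile 0.99, fixed seed), which set cutoffs of 133, 758 and 276 UMIs for hashtags 1, 2 and 3. A cell was kept with at least 500 genes, at least 1000 UMIs, under 15% mitochondrial UMIs, exactly 1 hashtag and no doublet call. Doublets were called with the Scrublet method, with 2 simulated doublets per cell and an expected share of 0.06. It called 513 of the 11301 cells past the filters (4.54%). In all, 4077 cells were kept. They were clustered with scanpy 1.11.5 and igraph 0.11.9 (10000 UMIs per cell, log scale, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.8, fixed seed, no integration). Genes of the lists below, mitochondrial genes and ribosomal protein genes were left out, so that the lists did not choose the clusters directly. Genes that vary together with the lists could still shape the clusters. A difference of list genes between classes or clusters is therefore not independent of the grouping. A cluster was named after a class only from marker genes fixed before the data were examined, from the mean log2 level of its markers over the mean of all clusters (CPM plus 10), which had to reach 1.5, with at least 3 markers at least 2-fold above the median cluster. The score limits were set after the data were examined. A cluster led by T cell lineage genes was given no name but T cell or NK cell. This left 1 cluster of 70 cells without a name, led by the neutrophil genes S100a9 and S100a8 and by Tcrg-C1, with 2, 53 and 15 cells of hashtags 1, 2 and 3. The 10301 cells past the filters with no doublet call, in every hashtag state but that of more than 1 hashtag, were clustered in the same way for the counts of hashtags per class. There the same rule left without a name a cluster of 373 cells with smooth muscle markers, led by Lck, Txk and Ccr9, that T cell lineage genes kept from being named smooth muscle-like.

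Raw UMI counts were summed per animal and class where at least 10 cells were present, and the sums, not the cells, were compared. The test was the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, its filter on low counts, the animal as a block), with Benjamini-Hochberg adjustment over all genes tested. A call needed an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The SE of a log2 fold change was its size divided by the root of F. Camera tests, two-sided, of limma 3.58.1 compared each list with the other genes, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. The comparisons, tests, cell filters, marker genes, gene lists and the rule for named genes were fixed before the data were examined. The 14 lists were mechanosensitive channels and sensors, integrins and focal adhesion, YAP/TAZ, Hippo and MRTF/SRF, actomyosin contraction and RhoA, elastic fibre, collagens and collagen processing, proteoglycans and matricellular proteins, matrix proteases and inhibitors, TGF-beta and BMP signalling, senescence and secretory factors, complement and chemokines, dissociation stress, lymphocyte ageing and sex chromosome genes.

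Genes were named by rule. In each list these were the 2 called genes with the largest change each way, among those with the same sign in every animal and at least 50 CPM (UMIs of a gene per 1e6 UMIs) in the higher class. In cluster comparisons it was 1 gene each way. Piezo1, Yap1, Eln, Col1a1, Itgb1, Cdkn1a and Cdkn2a were always named, and up to 10 list genes per class were named in the levels between animals. Some genes that the rule names are not reported here. Where a group held no UMI of a gene, the fold is a lower bound against 3 UMIs over the group. With 1 to 3 UMIs the ratio of the pooled counts is given with its 95% interval. Intervals of shares are exact binomial and those of counts exact Poisson. They and the floors of 3 counts cover counting error only. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs.

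The sums of 2 classes were paired because the hashtag names the animal. Across genes, the deviations of same-animal sums from their class means correlated between 0.016 and 0.351 in smooth muscle-like against fibroblast-like cells. They correlated between 0.024 and 0.197 in endothelial-like against smooth muscle-like cells and between -0.019 and 0.168 in the comparison of smooth muscle-like clusters. Macrophage-like and fibroblast-like sums shared 2 animals, with a correlation of 0.089. The pairing therefore rests on the reference table and was weak in the values.

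The fit was tested on simulated data with the depths of each comparison. Counts were drawn gene by gene from the spread fitted to each gene, with no animal effect and no correlation between genes. How the fit and the list tests behave with either was therefore not tested. Without simulated changes edgeR made 0 false calls in every comparison, and no list was called. With 100 genes changed by 1.5 on the log2 scale it recovered 86% in smooth muscle-like against fibroblast-like cells, 95% in endothelial-like against smooth muscle-like cells, 27% in macrophage-like against fibroblast-like cells and 85% between smooth muscle-like clusters. At 3 on the log2 scale it recovered 84% in the macrophage-like comparison and 100% in the others. False calls in the runs with changes numbered 1, 5, 2 and 1 in these comparisons, in the order above.

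Alternatives were the fit without the block, DESeq2 1.42.0 in place of edgeR or for its size factors, no filter on low counts, no minimum fold, each animal left out, equal cell numbers, other mitochondrial and gene limits, no doublet removal, Leiden resolutions of 0.4 and 1.2, list genes kept in clustering, and other hashtag rules. Some were added after seeing the data, among them the removal of cells with T cell RNA (at least 3 UMIs of the T cell markers, Rag1 or Ptprc), of smooth muscle-like cluster 9 and of cells under 2 times the hashtag cutoff, the MULTIseqDemux caller, and pools of cells of every hashtag state. The planned comparison of 2 fibroblast-like clusters could not be run because the kept fibroblast-like cells formed 1 cluster. Macrophage-like cells of the animal of 81 weeks were not used in a test because only 6 were kept. In smooth muscle-like, fibroblast-like, endothelial-like and T cell-like cells every hashtag had UMIs of Xist and 0 of the Y-linked Ddx3y, so sex gave no check of the hashtags. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.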

Results

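Single-cell gene expression was measured in the ascending thoracic aorta, the stretch of the aorta next to the heart, of 3 aged wildtype mice. The title of the series concerns mechanosensing and mechanoadaptation during ageing. The files hold aged animals alone, so age could not be compared, and the comparisons here are between cell classes of the same animals. The 26916 barcodes held 142108011 gene UMIs, with a median of 2975 UMIs per barcode (range 900 to 104654) and a median mitochondrial share of 15.9%. The filters on genes, UMIs and mitochondrial share left 11301 barcodes. Exactly 1 hashtag and no doublet call left 4077 cells. These were 549 cells with 4928805 UMIs for the animal of 81 weeks, 2524 cells with 17300274 UMIs for that of 84 weeks and 1004 cells with 7541716 UMIs for that of 88 weeks.

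The kept cells fell into 24 clusters. T cell-like cells were the most numerous class with 1667 cells, followed by 937 endothelial-like, 772 smooth muscle-like, 238 fibroblast-like and 203 erythroid-like cells. The remaining named classes held 58 epithelial-like, 32 mesothelial-like, 31 macrophage-like, 18 B cell-like, 17 NK cell-like, 17 pericyte-like and 17 dendritic-like cells. The B cell-like cluster was led by Igkc, Iglc1, Igha and Jchain, and scored 5.51 for B cell and 4.10 for plasma cell markers. T cell-like cells made up 6.19% (95% interval 4.33 to 8.55) of the cells of the animal of 81 weeks, 51.0% (49.1 to 53.0) at 84 weeks and 34.4% (31.4 to 37.4) at 88 weeks. Their largest cluster was led by Rag1, a recombinase of developing lymphocytes, with Cd4 and Cd8b1, and Mki67, a gene of dividing cells, was detected in 39.9% ± 4.10 (SD, n = 3) of T cell-like cells thinned to 1000 UMIs. Endothelial-like cells made up 44.1% (39.9 to 48.3), 15.9% (14.5 to 17.4) and 29.2% (26.4 to 32.1) of the cells of the animals of 81, 84 and 88 weeks. Smooth muscle-like cells made up 28.1% (24.3 to 32.0), 16.1% (14.7 to 17.6) and 21.1% (18.6 to 23.8), and fibroblast-like cells 7.83% (5.73 to 10.4), 5.82% (4.94 to 6.81) and 4.78% (3.55 to 6.29). Over the 3 animals the mean shares were 30.5% ± 22.7 for T cell-like, 29.7% ± 14.1 for endothelial-like, 21.8% ± 6.01 for smooth muscle-like, 6.15% ± 1.55 for fibroblast-like, 4.59% ± 0.869 for erythroid-like and 0.954% ± 0.427 for macrophage-like cells (SD, n = 3). With 1 pool and 1 animal per age there is no test between animals. T cell-like cells are not shown to belong to the wall of the aorta.

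**Figure D1:**
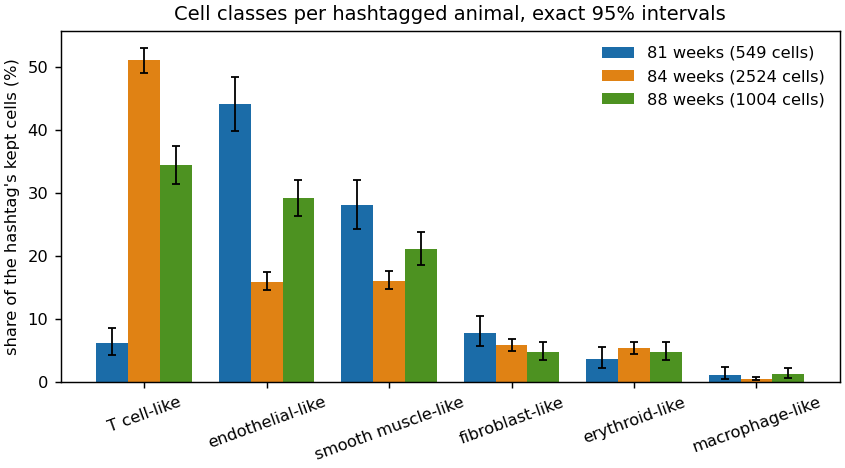
Bars give the share of each hashtag's kept cells (percent, vertical axis) in 6 cell classes (horizontal axis) for the animals of 81, 84 and 88 weeks, and error bars are exact 95% binomial intervals. T cell-like cells ranged from 6.19% to 51.0%, the widest range of the 6 classes.

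These shares follow from which cells carried a hashtag, and the classes differed widely in that. Among 10301 cells with no doublet call, of every hashtag state but that of more than 1, smooth muscle-like cells were the most numerous class with 45.7% (44.7 to 46.7), ahead of T cell-like (18.1%), fibroblast-like (12.5%) and endothelial-like cells (10.6%). Only 9.62% (8.79 to 10.5) of the 4709 smooth muscle-like cells and 16.3% (14.3 to 18.4) of the 1289 fibroblast-like cells had exactly 1 hashtag, against 89.5% (87.5 to 91.3) of 1095 endothelial-like and 90.7% (89.3 to 92.0) of 1865 T cell-like cells. A further cluster of 373 cells had 10 of 10 smooth muscle markers up but was led by Lck, Txk and other genes of T cells, and so was left without a name. Of its cells 19, 227 and 51 had hashtag 1, 2 or 3 alone and 76 had none. With it smooth muscle-like cells made up 49.3% (48.4 to 50.3) of all cells, and 14.8% (13.8 to 15.8) of 5082 had exactly 1 hashtag. T cell RNA was then found in 41.7% (38.2 to 45.4) of those with 1 hashtag and 5.42% (4.77 to 6.14) of those with none, and without this cluster in 9.05% (6.57 to 12.1) and 4.11% (3.54 to 4.75). In fibroblast-like cells it was found in 52.4% (45.4 to 59.3) and 6.12% (4.76 to 7.72). Clustering of the kept cells alone set no such cluster with smooth muscle markers apart. Its 772 smooth muscle-like cells, 320 (41.5%) of them with T cell RNA, all entered the tests below. The hashtag counts of the kept cells had a median of 1.37 times the cutoff in smooth muscle-like, 1.48 times in fibroblast-like, 1.57 times in erythroid-like and 1.68 times in T cell-like cells, against 2.99 times in endothelial-like cells. The shares of T cell-like cells per animal thus rest on counts near the cutoff too, with 37.0% of these cells under 1.5 times. The sums of smooth muscle-like and fibroblast-like cells are therefore called hashtag sets below. The tests measure the spread between these sets of cells, which is not shown to be the spread between animals.

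**Figure D2:**
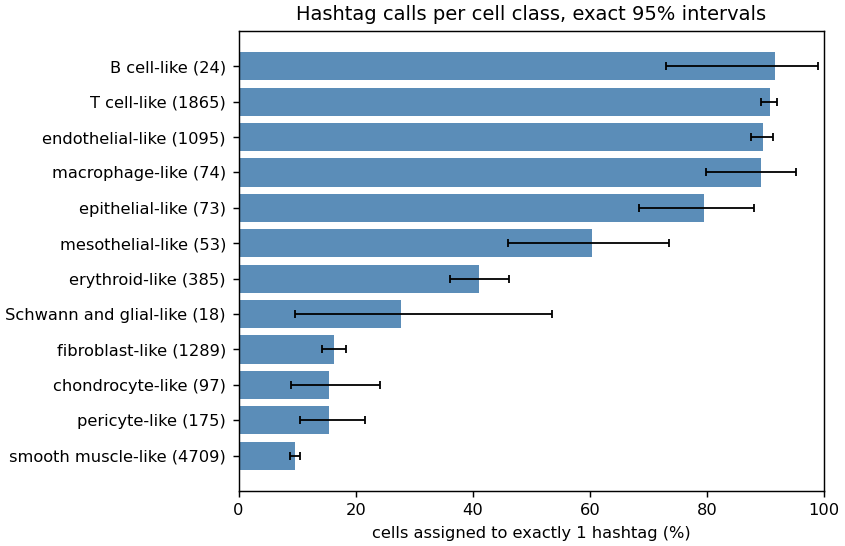
Bars give the percent of cells assigned to exactly 1 hashtag (horizontal axis) in each cell class (vertical axis, number of cells in parentheses), with exact 95% binomial intervals. Smooth muscle-like cells had 9.62%, not counting the unnamed cluster of 373 cells, and T cell-like cells had 90.7%.

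Smooth muscle-like cells were compared with fibroblast-like cells to ask which mechanosensing and matrix genes distinguish the contractile cells of the wall from its matrix-producing cells. More of the called list genes of contraction and adhesion were higher than lower in smooth muscle-like cells, and more of those of the extracellular matrix, its proteases and complement were lower, but with an estimated correlation 0 lists were called. Elastin (Eln), the core protein of elastic fibres, was among the matrix genes that went the other way. Eln had 1249 ± 73.5 CPM in smooth muscle-like against 551 ± 48.3 CPM in fibroblast-like cells (SD, n = 3). The log2 fold change was 1.30 ± 0.09 (SE, adjusted p = 1.1e-12, higher in 3 of 3 sets). Fibroblast-like clusters of every hashtag state, pooled with no test, differed in Eln, as given under other observations. This fold is thus an average over their mix. Col1a1, the main chain of fibrillar type I collagen, lay lower in smooth muscle-like cells with a log2 fold change of -1.56 ± 0.09 (496 ± 37.5 against 1592 ± 166 CPM). Itgb1, the beta subunit shared by many integrins, lay higher by 1.98 ± 0.09 on the log2 scale (1708 ± 54.6 against 473 ± 15.1 CPM). Of 9986 genes tested, 994 were called higher and 1228 lower in smooth muscle-like cells, and of 195 list genes tested 53 were higher and 63 lower.

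Of 18 genes of actomyosin contraction and RhoA tested, 15 were higher and 0 lower, led by Actg2, a smooth muscle actin (log2 fold change 5.19 ± 0.21), and Kcnmb1, a subunit of a calcium-activated potassium channel (5.04 ± 0.25, and 5.81 without the set of 88 weeks). The camera test put the list above the other genes (adjusted p = 5.1e-20, and 0.154 with an estimated correlation). Of 26 integrin and focal adhesion genes, 17 were higher and 2 lower (adjusted p = 1.9e-11, and 0.161 with an estimated correlation). Itga3, an alpha integrin, was higher by 4.46 ± 0.39 (5.46 without the set of 81 weeks and 3.56 without that of 84 weeks), and Itga7, a laminin-binding integrin, had 519 UMIs in smooth muscle-like and 0 in fibroblast-like cells, at least 35.5-fold higher against 3 UMIs over the group. Of 20 genes of YAP/TAZ, Hippo and MRTF/SRF, 5 were higher and 0 lower, among them Ccn1 (2.92 ± 0.17) and Ccn2 (1.95 ± 0.09), secreted matricellular proteins and targets of YAP. The list as a whole was not called (adjusted p = 0.068), and Yap1 itself had 38.5 ± 3.89 against 30.3 ± 0.666 CPM (log2 fold change 0.41 ± 0.21, adjusted p = 0.13). Of 12 mechanosensitive channels and sensors, 1 was higher and 3 lower (adjusted p = 0.56), with Pkd2, a cation channel of the polycystin family, at -1.62 ± 0.13. The mechanically gated channel Piezo1 had 8.70 ± 1.05 against 16.3 ± 7.69 CPM (log2 fold change -0.90 ± 0.35, adjusted p = 0.041, lower in 2 of 3 sets), short of the fold minimum of a call. It reached a call, at -1.21, without the set of 88 weeks.

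Among 18 elastic fibre genes, 2 were higher (Eln and Ltbp1, a latent TGF-beta binding protein, 1.47 ± 0.11) and 9 lower, led by the fibulins Fbln1 (-5.68 ± 0.14) and Efemp1 (-5.29 ± 0.18). The list lay lower (adjusted p = 2.9e-04, and 0.154 with an estimated correlation). Of 18 collagen genes 3 were higher and 8 lower (adjusted p = 2.1e-05, and 0.154 with an estimated correlation). The basement membrane collagens Col18a1 (3.90 ± 0.16) and Col4a2 (1.63 ± 0.13) were higher and Col14a1, which binds collagen fibrils, was lower (-2.73 ± 0.10). Of 15 proteoglycan and matricellular genes 2 were higher and 7 lower (adjusted p = 0.0042, and 0.233 with an estimated correlation). Postn, or periostin, was higher (2.36 ± 0.12), and Fmod, or fibromodulin, a small proteoglycan on collagen fibrils, was lower (-7.27 ± 0.27). Cilp had 2 UMIs in smooth muscle-like and 90 in fibroblast-like cells, a ratio of CPM of 219 (interval 59.0 to 1839). Of 11 matrix proteases and inhibitors 1 was higher, Adamts1 (1.32 ± 0.14), and 8 were lower, led by Mmp2 (-4.92 ± 0.14) and Mmp3 (-3.79 ± 0.20, and -4.70 without the set of 84 weeks) (adjusted p = 2.8e-08, and 0.154 with an estimated correlation). Adamts1 fell short of the fold minimum, at 0.94, with under 10% mitochondrial UMIs. Of 13 complement and chemokine genes 0 were higher and 12 lower (adjusted p = 8.0e-14, and 0.154 with an estimated correlation), among them complement C3 (-7.10 ± 0.14) and the eotaxin gene Ccl11 (-8.55 ± 0.29, with -9.16 without the set of 81 weeks and -7.93 without that of 88 weeks).

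Of 16 TGF-beta and BMP signalling genes 1 was higher and 5 were lower, led by the receptor genes Acvrl1 (-1.91 ± 0.21) and Tgfbr2 (-1.54 ± 0.12). This list was not called (adjusted p = 0.19). Of 9 senescence and secretory genes 2 were higher and 6 lower (adjusted p = 0.024, and 0.233 with an estimated correlation). Igfbp7 was higher (1.19 ± 0.08, but 0.89 and not called without doublet removal), and Igfbp3 (-6.12 ± 0.37, and -6.81 without the set of 81 weeks) and Igfbp5 (-5.49 ± 0.13) were lower. These 3 encode binding proteins of insulin-like growth factors. Cdkn1a, which encodes the cell cycle inhibitor p21, was lower (-1.14 ± 0.15, 69.9 ± 15.4 against 154 ± 29.7 CPM), but it fell short of the fold minimum without the set of 84 weeks (-0.74). Dissociation stress genes, which rise during enzymatic digestion, were higher as a list (5 of 15 higher and 3 lower, adjusted p = 0.031, and 0.346 with an estimated correlation). The heat shock gene Hspa1a (3.44 ± 0.19) and Atf3 (3.19 ± 0.23) were higher and the immediate early genes Ier2 (-1.14 ± 0.16) and Junb (-1.09 ± 0.18) lower. Ier2 (-0.69) and Junb (-0.15) lost their calls with hashtags of at least 2 times the cutoff. No gene was called among 3 tested of lymphocyte ageing (adjusted p = 0.73) and 2 of the sex chromosomes (adjusted p = 0.16). Adjusted over the list alone, each of the 14 lists had the same counts. Without cells holding T cell RNA, 863 genes were higher and 993 lower, and without smooth muscle-like cluster 9, 997 and 1224. With hashtags of at least 2 times the cutoff the counts fell to 566 and 517. These 3 settings were chosen after seeing the data. All these p-values rest on 3 hashtag sets per class of 395860 to 5314072 UMIs and measure the spread between those sets, not one shown to be between animals.

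Endothelial-like cells were compared with smooth muscle-like cells. Of the 937 endothelial-like cells 650 lay in a cluster led by Cxcl9, Gpihbp1 and Fabp4, and 72 in one led by Cytl1, Bmp4 and Vwf. Which of them line the aorta itself was not tested, so the folds below are not shown to be those of its lining. Sensors of flow and force were among the genes higher in endothelial-like cells. Piezo1 had 76.1 ± 3.57 CPM in endothelial-like and 8.70 ± 1.05 CPM in smooth muscle-like cells (SD, n = 3), a log2 fold change of 3.09 ± 0.16 (SE, adjusted p = 1.5e-09, higher in 3 of 3 sets). Notch1 (4.32 ± 0.16) and Plxnd1 (3.52 ± 0.21), receptors that take part in the endothelial response to flow, were higher too, and the polycystin Pkd1 was lower (-1.48 ± 0.14). Of 13 mechanosensitive genes tested, 4 were higher and 4 lower, and the list as a whole was not called (adjusted p = 0.94, with a median log2 fold change of -0.21 and a mean of 0.53). Of 10469 genes tested, 1666 were called higher and 1698 lower, and of 194 list genes 41 were higher and 88 lower.

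Adhesion and contraction genes lay mainly lower in endothelial-like cells. Of 25 integrin and focal adhesion genes 4 were higher and 17 lower (adjusted p = 2.5e-04, and 0.456 with an estimated correlation), with Itga8 (-5.09 ± 0.10), Itgb3 (-4.22 ± 0.23) and Itgb1 (-1.08 ± 0.08) lower, and the focal adhesion kinase gene Ptk2 (2.32 ± 0.13) and the adaptor gene Pxn, or paxillin (2.14 ± 0.15), higher. Of 18 actomyosin genes 1 was higher, the tropomyosin Tpm4 (1.48 ± 0.09), and 15 were lower, led by the potassium channel genes Kcnma1 (-5.48 ± 0.27) and Kcnmb1 (-5.14 ± 0.19) (adjusted p = 6.1e-10, and 0.322 with an estimated correlation). Of 21 YAP/TAZ, Hippo and MRTF/SRF genes 7 were higher and 3 lower (adjusted p = 0.55, median 0.34 and mean -0.02 on the log2 scale). Wwtr1, which encodes TAZ (1.93 ± 0.10), and Amotl2, an angiomotin (2.54 ± 0.18), were higher and Ccn2 was lower (-4.39 ± 0.10). Yap1 had 34.5 ± 4.68 against 38.5 ± 3.89 CPM (-0.18 ± 0.16, adjusted p = 0.36).

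Matrix genes lay mainly lower as well. Of 18 elastic fibre genes 2 were higher and 14 lower (adjusted p = 1.6e-05, and 0.425 with an estimated correlation). Eln (-2.90 ± 0.19), Mfap4 (-4.48 ± 0.16), a microfibril protein, and the crosslinking enzyme gene Loxl1 (-3.76 ± 0.15) were lower, and Fbln2 was higher (3.73 ± 0.16). Of 17 collagen genes 3 were higher and 11 lower (adjusted p = 0.0011, and 0.425 with an estimated correlation). Col18a1 (-4.36 ± 0.11) and Col1a1 (-4.32 ± 0.14) were lower, and the basement membrane collagen Col4a1 (1.04 ± 0.09) and Plod1, a lysyl hydroxylase (1.76 ± 0.14), were higher. Col4a1 fell just short of the fold minimum, at 0.99, without the sums of 81 weeks and without those of 88 weeks. Of 13 proteoglycan and matricellular genes 1 was higher and 10 lower, with Ogn (-4.71 ± 0.11) and Postn (-3.71 ± 0.21) among them (adjusted p = 1.0e-04, and 0.322 with an estimated correlation). Of 11 proteases and inhibitors 1 was higher, the inhibitor Timp4 (5.26 ± 0.12), and 5 lower, with the procollagen peptidase gene Adamts2 and the inhibitor gene Timp2 (-1.59 ± 0.16) among them (adjusted p = 0.42).

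Signalling genes went both ways. Of 16 TGF-beta and BMP genes 6 were higher and 4 lower (adjusted p = 0.094). The endothelial co-receptor gene Eng, or endoglin (4.41 ± 0.12), and Acvrl1 (2.90 ± 0.13) were higher, and Tgfb3 (-3.36 ± 0.19) was lower. Of 13 complement and chemokine genes 6 were higher and 2 lower (adjusted p = 0.16). The adhesion molecule gene Icam1 (5.02 ± 0.31, and 6.28 without the sums of 84 weeks) and the chemokine gene Cxcl12 (4.43 ± 0.17) were higher, and the complement inhibitor gene Serping1 was lower (-1.56 ± 0.12). Of 10 senescence and secretory genes 2 were higher and 2 lower (adjusted p = 0.45). Cdkn1a had 661 ± 270 CPM in endothelial-like cells, a log2 fold change of 3.19 ± 0.25, Igfbp3 was higher (5.97 ± 0.24) and Igfbp7 lower (-1.40 ± 0.08). Pooled Cdkn1a was 851 CPM in the largest endothelial-like cluster but 33.0 CPM in the one led by Cytl1, Bmp4 and Vwf. Of 15 dissociation stress genes 4 were higher and 2 lower (adjusted p = 0.080). The immediate early genes Ier2 (2.05 ± 0.12) and Jun (1.68 ± 0.09) were higher and Fos lower (-1.44 ± 0.18). Fos and Itgb1 fell short of the fold minimum, both at -0.93, with under 10% mitochondrial UMIs. Lymphocyte ageing (3 tested, adjusted p = 0.63) and sex chromosome genes (2 tested, adjusted p = 0.13) had no call. Adjusted over the list alone, each list had the same counts. T cell RNA was found in 10.1% of endothelial-like and 41.5% of smooth muscle-like cells. Without cells holding it 1697 genes were higher and 1670 lower, and without smooth muscle-like cluster 9, 1680 and 1696 (both chosen after seeing the data). The sums held 1263147 to 5314072 UMIs, and those of smooth muscle-like cells are hashtag sets not shown to be animals.

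**Figure D3:**
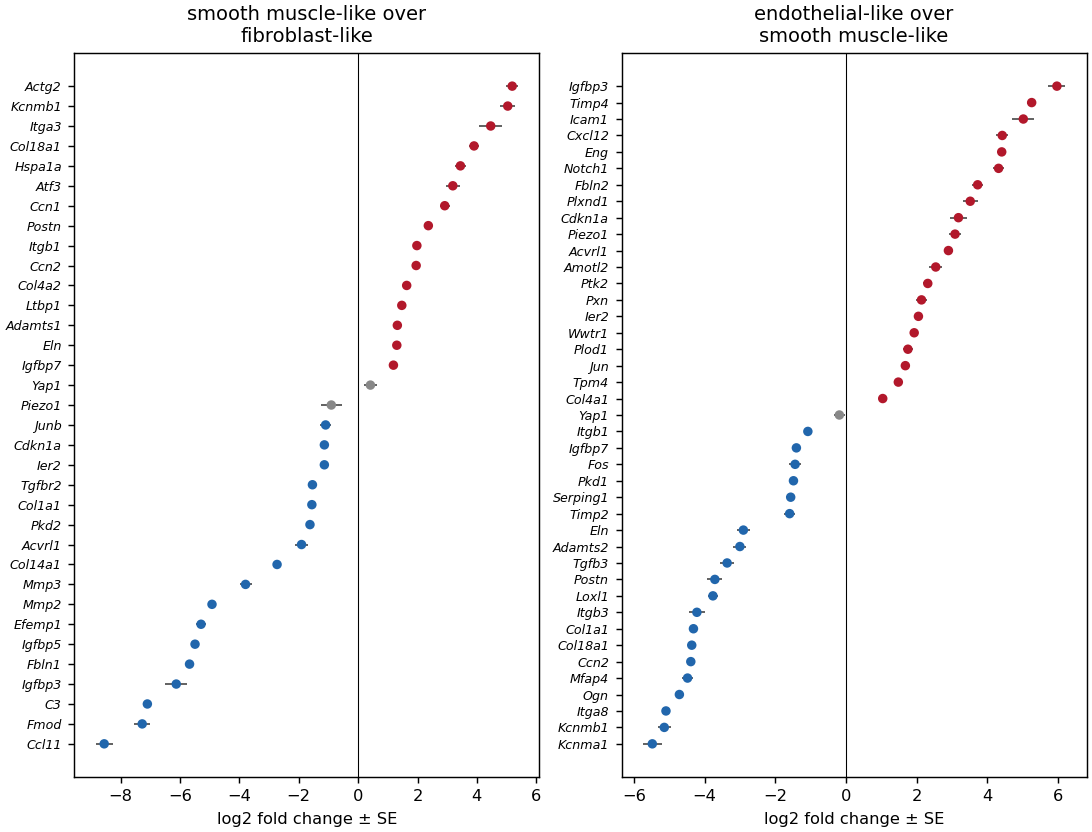
Points give the edgeR log2 fold change (horizontal axis) of the named genes (vertical axis) with its SE, for smooth muscle-like over fibroblast-like cells on the left and endothelial-like over smooth muscle-like cells on the right, 3 sums per class. Red points were called higher, blue points lower and grey points not called. Genes with 3 or fewer UMIs in a class and those not reported in the text are left out. Eln lies at 1.30 on the left and at -2.90 on the right, and Piezo1 at -0.90 and 3.09.

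Macrophage-like cells were compared with fibroblast-like cells, but only 12 cells of the animal of 84 weeks and 13 of that of 88 weeks entered, with 72554 and 76589 UMIs. Most list genes of the matrix were lower in macrophage-like cells. Of 18 elastic fibre genes 17 were lower and 0 higher (adjusted p = 4.2e-11), of 17 collagen genes 13 lower and 0 higher (adjusted p = 4.4e-08), and of 14 proteoglycan and matricellular genes 14 lower (adjusted p = 1.3e-10). With an estimated correlation each of these 3 adjusted p was 0.476. Eln was lower by a log2 fold change of -3.58 ± 0.50 (52.6 ± 54.9 CPM, SD, n = 2, against 551 ± 48.3 CPM, n = 3). Genes with 0 UMIs in macrophage-like cells were lower at least by the following folds, against 3 UMIs over the group. They were Fbln2 (20.2), Loxl1 (14.9), Col6a3 (10.4), Col5a2 (11.4), Aspn (16.5), Fmod (7.22), Adamts5 (23.7), Mmp3 (10.9), Parva (4.43), Wwtr1 (5.44), Amotl1 (4.24), Tgfb3 (5.88), Igfbp3 (4.14), C1s1 (13.4), Ccl11 (9.16) and Yap1 (1.52). Col1a1 had 1 UMI against 3193, a ratio of 235 (interval 42.1 to 9269), and Igfbp5 2 against 4949, a ratio of 182 (50.3 to 1502). Fermt2 had 1 UMI against 473, a ratio of 34.8 (6.21 to 1376), and Tgfbr3 1 against 307, a ratio of 22.6 (4.02 to 894).

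Single genes were higher in macrophage-like cells. Mmp12, the macrophage elastase, had 31 UMIs in macrophage-like cells and 0 in fibroblast-like cells, at least 141-fold higher. Mmp9 had 28 UMIs against 1, a ratio of 381 (63.0 to 15583), and Itgax, a leukocyte integrin, 15 against 1, a ratio of 204 (31.4 to 8594). Of 14 proteases and inhibitors 3 were higher and 10 lower (adjusted p = 0.0034, and 0.610 with an estimated correlation). Of 12 complement and chemokine genes 2 were higher, Vcam1 (3.09 ± 0.34) and Cxcl16 (2.35 ± 0.46), and 8 lower (adjusted p = 0.017, and 0.610 with an estimated correlation). Of 14 TGF-beta and BMP genes 2 were higher, Tgfb1 (2.80 ± 0.46) and Tgfbr1 (1.98 ± 0.40), and 3 lower (adjusted p = 0.37). Of 9 senescence and secretory genes 5 were lower (adjusted p = 0.033, and 0.610 with an estimated correlation). Cdkn1a had 2 UMIs against 339, a ratio of 12.5 (3.42 to 103), and Cdkn2a, which encodes the cell cycle inhibitor p16, 5 UMIs against 2, a ratio of 34.0 (5.57 to 357). A Cdkn2a UMI was found in 3 of 13 macrophage-like cells at 88 weeks and 0 of 12 at 84 weeks, so this ratio rests on 1 animal. Of 15 YAP/TAZ and Hippo genes 2 were higher, Stk4 (1.64 ± 0.47) and Mob1a (1.11 ± 0.41), and 6 lower (adjusted p = 0.35). Of 23 integrin and adhesion genes 1 was higher, talin (Tln1, 1.42 ± 0.33), and 5 lower (adjusted p = 0.065), and Itgb1 had 389 ± 4.09 against 473 ± 15.1 CPM (-0.39 ± 0.33, adjusted p = 0.47).

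Of 7 mechanosensitive genes 2 were lower in macrophage-like cells, Pkd2 (-2.83 ± 0.66) and Pkd1 (-1.86 ± 0.58) (adjusted p = 0.83). Piezo1 did not pass the filter on low counts. Of 14 actomyosin genes 2 were lower, with Cald1 at -2.31 ± 0.42 (adjusted p = 0.37), and of 11 dissociation stress genes 3, with Egr1 at -3.29 ± 0.59 and Jund at -1.65 ± 0.36 (adjusted p = 0.065). Lymphocyte ageing had 1 of 3 genes higher and 1 lower (adjusted p = 0.53), and sex chromosome genes 0 of 2 called (adjusted p = 0.70). Of 6777 genes tested, 660 were higher and 885 lower, and of 173 list genes 11 were higher and 89 lower. Adjusted over the list alone, the elastic fibre list had 18 genes lower, collagens 1 higher and 14 lower, proteases 11 lower, dissociation stress 4 lower, YAP/TAZ and Hippo 3 higher and actomyosin 1 lower, and the other counts were equal. With 1 residual degree of freedom and 27% recovery of simulated changes of 1.5 on the log2 scale, this comparison was the least certain. Of its 37 named calls 17 were lost in at least 1 alternative, those of Pkd2 and Pkd1 included. With under 10% mitochondrial UMIs the lost calls were, among others, Vcam1 (0.29), Tgfbr1 (0.64), Cxcl16 (1.60), Stk4 (1.35) and Mob1a (1.03), and Cald1 (0.17) turned its sign there. With the DESeq2 Wald test Mmp12, Cxcl16, Tgfbr1, Stk4, Mob1a and Tln1 were among those lost.

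Within smooth muscle-like cells the 2 largest clusters were compared by number, for list genes alone. Cluster 2 with 611 cells was led by Mylk4, Itga8 and Npnt. Cluster 9 with 161 cells was led by Actc1, Tnnt2 and Des, that is by 2 genes of the cardiomyocyte markers and 1 of the smooth muscle markers. Cluster 2 made up 22.8% (19.3 to 26.5), 12.6% (11.3 to 13.9) and 16.8% (14.6 to 19.3) of the cells of the animals of 81, 84 and 88 weeks, and cluster 9 5.28% (3.57 to 7.50), 3.53% (2.84 to 4.32) and 4.28% (3.12 to 5.73). Of 182 list genes tested, 7 were higher and 9 lower in cluster 2. Fibronectin (Fn1), a cell-adhesive matrix protein, was higher in cluster 2 with 764 ± 39.3 against 172 ± 6.51 CPM (SD, n = 3), a log2 fold change of 2.14 ± 0.10 (SE, adjusted p = 1.0e-19, 3 of 3 sets). The crosslinking enzyme gene Lox was higher (1.05 ± 0.18). Fbln1 (-2.63 ± 0.28), Thbs1, or thrombospondin (-2.90 ± 0.32), Igfbp5 (-1.55 ± 0.21), Cdkn1a (-1.26 ± 0.16) and the aggrecanase gene Adamts5 (-1.03 ± 0.14) were lower. Eln had 1349 ± 47.2 against 779 ± 257 CPM (0.86 ± 0.10, adjusted p = 2.4e-08), short of the fold minimum. It reached a call, at 1.03, without the set of 81 weeks, and Lox (0.76) and Igfbp5 (-0.95) lost theirs without that of 84 weeks, where Thbs1 moved to -2.29. Adamts5 lost its call at equal cell numbers (-0.85).

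As lists, proteoglycans and matricellular genes (4 of 13 higher and 1 lower, adjusted p = 1.0e-09, and 0.332 with an estimated correlation) and elastic fibre genes (2 of 17 higher and 1 lower, adjusted p = 1.4e-04, and 0.346 with an estimated correlation) lay higher in cluster 2. So did collagens (0 of 16 called, adjusted p = 4.1e-07, and 0.346 with an estimated correlation) and integrins (0 of 25 called, adjusted p = 2.5e-05, and 0.332 with an estimated correlation). Complement and chemokines lay lower (1 of 9 higher and 3 lower, adjusted p = 0.0010, and 0.346 with an estimated correlation). Mechanosensitive genes (0 of 12 called, adjusted p = 0.77), YAP/TAZ and Hippo (0 of 19, adjusted p = 0.070), actomyosin (0 of 18, adjusted p = 0.97), TGF-beta and BMP (0 of 16, adjusted p = 0.71), dissociation stress (0 of 15, adjusted p = 0.93) and sex chromosome genes (0 of 2, adjusted p = 0.92) had no call. Proteases had 1 of 11 lower (adjusted p = 0.92), senescence genes 2 of 8 lower (adjusted p = 0.38) and lymphocyte ageing 1 of 2 lower (adjusted p = 0.41). Adjusted over the list alone, proteases had 1 more gene higher and the other counts were equal. Itgb1 (0.37 ± 0.07, adjusted p = 1.4e-04), Col1a1 (0.36 ± 0.10, adjusted p = 0.021), Piezo1 (-0.84 ± 0.41, adjusted p = 0.32) and Yap1 (0.12 ± 0.22, adjusted p = 0.88) were not called, and Cdkn2a had 0 UMIs in both clusters. Without the set of 84 weeks or that of 88 weeks the list genes higher fell from 7 to 4. The sets held 285425 to 4278767 UMIs and are not shown to be animals.

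Levels of list genes were set side by side between animals within each class, as CPM with 95% Poisson intervals and with no test. In endothelial-like cells 15 of 106 list genes of at least 50 CPM differed at least 2-fold between the highest and the lowest animal. Thbs1 ranged widest, from 14.3 CPM (8.45 to 22.5) at 81 weeks through 45.6 (37.0 to 55.6) at 84 weeks to 199 (179 to 221) at 88 weeks, 14.0-fold. The adhesion molecule gene Vcam1 had 101, 82.7 and 230 CPM, Fbln5 124, 135 and 301, Eln 109, 167 and 260, and Fn1 61.0, 105 and 145, at 81, 84 and 88 weeks. Igfbp3 had 124, 63.0 and 42.7 CPM, Egr1 268, 166 and 103, and Col15a1 110, 31.0 and 68.2. In fibroblast-like cells 22 of 141 list genes differed 2-fold, with Ccl2, a monocyte chemokine, at 177 CPM (138 to 223), 9.77 (5.05 to 17.1) and 4.93 (0.597 to 17.8). Col8a1, Col12a1, Stk4, Igfbp3, Timp1, Icam1, Cilp, Nr4a1 and Mmp3 followed with ratios of 2.50 to 17.9. In T cell-like cells 6 of 46 differed (Dnajb1, Egr1, Smad2, Stk4, Col1a2 and Tpm4, ratios of 2.13 to 2.87), on 34 cells for the animal of 81 weeks. In smooth muscle-like cells 1 of 119 differed, the immediate early gene Fosb (24.8, 50.1 and 54.3 CPM). The endothelial-like clusters also differed in share between animals, as weighed under other observations. Within the largest of them the ratio of the highest to the lowest animal was 1.73 for Eln, 1.66 for Fbln5 and 1.40 for Fn1. It was 2.01 to 8.73 for Col15a1, Egr1, Vcam1, Igfbp3 and Thbs1. With 1 animal per age and hashtag sets for smooth muscle-like and fibroblast-like cells, age, animal and chance cannot be parted.

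Cdkn1a and Cdkn2a, 2 cell cycle inhibitor genes of the senescence list, were counted per cell after thinning each to 1000 UMIs. Senescence itself was not measured, and a UMI of either gene does not by itself show a senescent cell. A Cdkn1a UMI was found in 44.4% ± 10.9 of endothelial-like, 5.00% ± 2.42 of smooth muscle-like and 8.75% ± 1.72 of fibroblast-like cells (SD, n = 3). T cell-like cells, taken as background, had 1.45% ± 1.30, or 0.660% over all 1667 cells. Per animal the endothelial-like share was 32.6% (26.8 to 38.9) at 81 weeks, 54.2% (49.2 to 59.2) at 84 weeks and 46.4% (40.6 to 52.3) at 88 weeks. The endothelial-like clusters were not alike. Pooled Cdkn1a was 33.0 CPM in the Vwf-led cluster and 851 CPM in the largest, so the share does not hold for every endothelial-like cluster. Median depths before thinning were 4142 UMIs in endothelial-like, 11928 in smooth muscle-like, 7982 in fibroblast-like and 3827 in T cell-like cells. Without thinning the shares were 80.7%, 28.9% and 35.1% of endothelial-like, smooth muscle-like and fibroblast-like cells. Cdkn2a was not detected in 937 endothelial-like cells, which allows a share with a UMI of up to 0.393%, in 772 smooth muscle-like cells (up to 0.477%) or in 238 fibroblast-like cells (up to 1.54%) at this depth. In the summed counts Cdkn2a had 1 UMI in endothelial-like, 0 in smooth muscle-like and 2 in fibroblast-like cells, at or under the floor of 3, so no fold is given.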

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

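The tests of this part were chosen after the results were seen. Some of the cells past the filters entered none of the comparisons, and their numbers are given here because they lie outside the main measurement. Without a hashtag were 4256 smooth muscle-like and 1079 fibroblast-like cells, and 76 cells of the unnamed cluster of 373 with smooth muscle markers. A class of 97 chondrocyte-like cells appeared when cells of every hashtag state were clustered, led by Prg4, Chad, Comp and Col2a1, genes of cartilage and tendon matrix. Among the kept cells, 1667 were T cell-like, with a largest cluster led by Rag1, Cd4 and Cd8b1, and 58 were epithelial-like. Of the epithelial-like cells a cluster of 24 was led by Tbata, Prss16, Ccl25 and Psmb11, and a cluster of 20 by Bpifa1 and Scgb1a1, with 17 of these 20 cells from the animal of 81 weeks. Whether these cells belong to the wall of the aorta or to tissue taken with it was not tested. No other explanation for their presence was tested either.

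Few smooth muscle-like and fibroblast-like cells carried a hashtag. Lower depth of gene UMIs is argued against. The median was 11229 gene UMIs in smooth muscle-like and 7503 in fibroblast-like cells, and 4120 in endothelial-like cells. Gene UMIs do not measure hashtag UMIs, so these medians decide nothing about low hashtag counts. Low RNA of H2-K1 alone, a gene of the major histocompatibility complex, is argued against as the whole cause, since T cell-like cells had less of it (79.2 CPM) than smooth muscle-like (97.3) and fibroblast-like cells (271) and a hashtag in 90.7%, which with erythroid-like cells, 71.9% of the kept ones holding T cell RNA, made 4 of 21 pairs of classes with the lower share in the class with more, against 11 with the higher. With the unnamed cluster, hashtags brought by T cells caught in the same droplets stay open as a candidate explanation for 313 hashtagged smooth muscle-like cells with T cell RNA, since hashtag 2 made up 77.0% (71.9 to 81.5) of them and 77.1% of hashtagged T cell-like cells. They are argued against as the whole cause for 437 without T cell RNA, where hashtag 2 made up 35.9% (31.4 to 40.6). Low RNA of the hashtag antigens with Ptprc taken in cannot be told apart. The class with more had the higher share in 10 of 16 pairs ordered alike by both genes and the lower in 0. The genes order the 5 pairs left out oppositely, so these decide nothing. In the 4 contrary to H2-K1 the class with the higher share had more Ptprc, with 1326 CPM in T cell-like and 190 in erythroid-like cells. Smooth muscle-like cells had 9.64 CPM and fibroblast-like cells 52.9. In the remaining pair mesothelial-like cells had the higher share but less Ptprc (11.2 CPM) than fibroblast-like cells.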

How the results depend on the processing

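The 2 times cutoff, MULTIseqDemux, the sets without T cell RNA or without cluster 9, the pooling of every hashtag state, the stricter HTODemux quantile for shares and each alternative of the endothelial-like clusters were chosen after seeing the data. Of 2686 values of named genes under alternatives 20 reversed, 80 lost a call and 10 gained one. With every hashtag state pooled, without the unnamed cluster of 373 cells, 62 named values moved, 2 reversed and 53 kept. Of the other results under alternatives, such as counts and shares, 286 counted as the same, 30 moved, 32 were weaker and 9 stronger. Here the same means close to the main value. This was judged by the ratio to it for counts, by its SD for shares and by its interval for hashtag percentages. Direction and side of a threshold were not tested for these results. The cause was not tested except where the setting itself gives it.

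Without the fold minimum more genes pass by construction. Counts over all genes between clusters are also high by construction, because the clusters were formed from variable genes among them. In smooth muscle-like against fibroblast-like cells 1922 genes were higher and 1963 lower, in endothelial-like against smooth muscle-like cells 3093 and 3004 with 65 list genes higher, and between the smooth muscle-like clusters 278 and 258 with 37 list genes higher and 17 lower. With an estimated correlation 0 lists were called in each of these 3 comparisons and 0 in macrophage-like against fibroblast-like cells. With hashtags at 2 times the cutoff, and so fewer cells, 566 genes were higher and 517 lower in smooth muscle-like against fibroblast-like cells, and with MULTIseqDemux 805 were lower.

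In macrophage-like against fibroblast-like cells the DESeq2 Wald test called 231 genes higher and 329 lower with 5 list genes higher, equal cell numbers 292 and 312 with 5 list genes higher and 54 lower, and a mitochondrial share under 10% 367 and 428 with 5 and 58. Leiden resolution 1.2 called 427 and 417, MULTIseqDemux 386 and 461 with 4 list genes higher, and no Scrublet removal 545 lower. Between the smooth muscle-like clusters the DESeq2 Wald test called 37 and 36 with 2 list genes higher, and equal cell numbers 52 and 46 with 4. Leaving out each replicate gave 4 to 9 list genes higher there. For the Vwf-led endothelial-like cluster (811 and 764) equal cell numbers gave 365 and 353 and the DESeq2 Wald test 586 and 505. For the Sema3g-led cluster (175 and 84) the DESeq2 Wald test gave 113 and 32, equal cell numbers 118 and 58, no filter on low counts 202 and 142, no fold minimum 274 and 171, and leaving out replicate 3 135 and 56.

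Reversed in macrophage-like against fibroblast-like cells were Cald1 with a mitochondrial share under 10% (0.17) and with every hashtag state pooled (0.88), and Itgb1, not called, with a mitochondrial share under 10% (0.62), no Scrublet removal (0.32), Leiden resolution 1.2 (0.41), MULTIseqDemux (0.25) and pooling (0.94). The pooled macrophage-like class was another grouping of 74 cells, led by S100a9 and S100a8. It scored 4.99 for macrophage and 4.62 for neutrophil markers, so its values are not those of the same cells. The other reversed values were of genes not called. Between the smooth muscle-like clusters Yap1 lay at -0.17 to 0.37 when each replicate was left out (reversed without replicate 2) and at -0.12 without T cell RNA. In the Vwf-led endothelial-like cluster Itgb1 lay at -0.12 without the filter on low counts, -0.065 to 0.13 when each replicate was left out (reversed without 2) and -0.0057 at 2 times the cutoff, and Col1a1 at -0.70 to 0.86 (reversed without 1). In the Sema3g-led cluster Col1a1 lay at 0.0076 with DESeq2 and -0.46 to 0.62 when each replicate was left out (reversed without 2), Yap1 at -0.24 to 0.53 (reversed without 3), and Itgb1 at -0.059 to 0.11 (reversed without 1 and without 2), -0.050 without the filter on low counts and -0.014 at equal cell numbers.

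Shares moved with the filters. The mean share of T cell-like cells was 15.6% under the 80% rule, 13.6% under 10% mitochondrial UMIs and 44.2% with the loose filter. These count as the same only because the SD of the main value was wide (30.5% ± 22.7, n = 3). The 80% rule for hashtags gave 56.9% endothelial-like, 11.6% smooth muscle-like, 1.49% erythroid-like and 1.47% macrophage-like cells. It gave hashtags 1 and 3 only 10 and 127 of all barcodes, against 8854 for hashtag 2, so these means rest on few cells of the animals of 81 and 88 weeks. Under 10% mitochondrial UMIs gave 36.3% smooth muscle-like, 8.56% fibroblast-like and 2.09% macrophage-like cells, and the loose filter 14.5% smooth muscle-like and 4.04% fibroblast-like cells. MULTIseqDemux gave 15.6% smooth muscle-like, 2.71% erythroid-like and 1.78% macrophage-like cells, the stricter quantile gave 3.17% erythroid-like and 1.56% macrophage-like, and Leiden resolution 0.4 gave 3.21% erythroid-like. Barcodes with 1, more than 1 and no hashtag were 33.4%, 0% and 66.6% under the 80% rule, 36.9%, 2.93% and 60.2% at the stricter quantile, and 46.4%, 4.00% and 49.6% with MULTIseqDemux. Cells with a Cdkn1a UMI rose with depth by construction, to 64.2%, 9.07% and 18.6% of endothelial-like, smooth muscle-like and fibroblast-like cells at 2000 UMIs and 80.7%, 28.9% and 35.1% without thinning.

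The animal block moved no count by more than 1.5 times. Without it 993 genes were higher and 1199 lower in smooth muscle-like against fibroblast-like cells (994 and 1228 with it), 1667 and 1690 in endothelial-like against smooth muscle-like (1666 and 1698), 642 and 920 in macrophage-like against fibroblast-like (660 and 885), and 79 and 74 between the smooth muscle-like clusters (81 and 77). The 80% rule left no sums of at least 10 cells for the fits, macrophage-like cells without replicate 2 or 3 left no residual degrees of freedom, and 2 times the cutoff left too few macrophage-like cells and too few cells of the smooth muscle-like clusters. The comparison of fibroblast-like clusters was not run. In the macrophage-like comparison 27% of simulated changes of 1.5 on the log2 scale were recovered, against 86% in smooth muscle-like against fibroblast-like cells, and its low depth and its 1 residual degree of freedom were not parted as causes.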

Other observations

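The comparisons and tests of this part were chosen after the results were seen. Endothelial-like cells held clusters with different matrix genes. A cluster of 72 cells was led by Cytl1, Bmp4 and Vwf, the gene of von Willebrand factor. Against the largest endothelial-like cluster, 11 of its 13 elastic fibre genes tested were higher and 0 lower (adjusted p = 7.1e-09, and 0.390 with an estimated correlation). Eln was higher by 3.47 ± 0.19 on the log2 scale (796 ± 288 against 70.9 ± 19.3 CPM, SD, n = 3, 3 of 3 animals) and Thbs1 by 5.19 ± 0.34. Cdkn1a was lower (-4.58 ± 0.47, 36.1 ± 33.6 against 802 ± 305 CPM), and so was Col4a2 (-3.89 ± 0.24). Of 15 dissociation stress genes 2 were higher and 5 lower (median -0.64, adjusted p = 0.16), and of 14 collagen genes 6 were higher and 4 lower (adjusted p = 0.82). Thbs1 moved to 4.54 without the animal of 84 weeks and 6.18 without that of 88 weeks, and Cdkn1a to -5.48 without that of 81 weeks and -3.92 without that of 84 weeks. Of 6921 genes tested 811 were higher and 764 lower, on sums of 167782 to 1397918 UMIs. The clusters were formed from variable genes among these, so counts over all genes are high by construction and are no evidence for the clusters.

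A cluster of 176 cells was led by Rbp7, Sema3g and Cxcl12. Against the largest cluster, 175 of 6675 genes were higher and 84 lower, counts that the clustering on such genes raises by construction too. Fbln5, which joins elastic fibres to cells, was higher (3.29 ± 0.26, 362 ± 206 against 30.3 ± 7.45 CPM), as were Col8a1 (4.36 ± 0.32, and 5.35 without the animal of 88 weeks), Tgfb2 (3.08 ± 0.35) and Igfbp3 (2.26 ± 0.17). Of 7 senescence and secretory genes 3 were higher and 0 lower (adjusted p = 1.4e-05, and 0.398 with an estimated correlation), and Cdkn1a was not called (0.24 ± 0.10, adjusted p = 0.19). Timp4 was lower (-1.13 ± 0.14) and fell short of the fold minimum, at -0.95, without the animal of 81 weeks.

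Fibroblast-like cells of every hashtag state, summed with no test, formed a cluster of 729 cells led by Pi16 and one of 560 led by Dio2. The former had more C3 (2331 against 266 CPM), Fn1 (1038 against 191) and Efemp1 (378 against 74.2), and the latter more Eln (1059 against 274), Ccn2 (884 against 163) and Fmod (288 against 10.7). The 97 chondrocyte-like cells had 991 CPM of Comp, a cartilage matrix protein, and 901 of Thbs1, against 8.63 and 21.1 CPM in the Pi16-led cluster.

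List genes that differed between animals in endothelial-like cells were weighed against different shares of the clusters. The Vwf-led cluster made up 9.09%, 4.48% and 10.9% of the endothelial-like cells of the animals of 81, 84 and 88 weeks. Of 15 such genes 8 were under 2-fold within the largest cluster, with ratios of 1.02 to 1.73 there (Eln 1.73, against 2.40 over all endothelial-like cells), and for these the part of the cluster shares was not tested. Of the 7 still 2-fold, 5 had intervals apart within the largest cluster (Thbs1, Smad7, Cdkn1a, Igfbp3 and Egr1), which argues against cluster shares as the whole cause for these. The intervals cover counting error only, and Thbs1 rested on 35 UMIs there. Age and animal stay open, untested.

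Cdkn1a UMIs in endothelial-like cells were weighed against free RNA and a heat shock response. Free RNA is argued against, since 0.660% of T cell-like cells had a Cdkn1a UMI at the same depth, against 46.2% (43.0 to 49.5) of endothelial-like cells. A heat shock response during digestion cannot be told apart, since Cdkn1a CPM of cells without heat shock UMIs was 65.4% to 80.9% of that of cells with them over 3 animals in the largest cluster and 87.4%, 103% and 65.6% in the Sema3g-led one at 81, 84 and 88 weeks, and a response in cells with no captured heat shock UMI stays open. For UMIs of Atf3, Fos and Fosb, other genes that rise in digestion, these ratios were 81.5% to 91.5% and 58.8% to 87.4% over the 3 animals. In the Vwf-led cluster the heat shock ratios were 190% at 81 weeks and 224% at 88 weeks, on 5 to 8 Cdkn1a UMIs per group of cells. That for Atf3, Fos and Fosb was 129% at 88 weeks, on 9 and 5 UMIs. No biological explanation was tested.

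Other splits of the 6 sums into 3 and 3, fitted without the animal block, are too few for a share under 0.05, with 1 of 10 splits, the real one, calling as many genes in each comparison. The real split called 2192 genes in smooth muscle-like against fibroblast-like cells (highest other 0), 3357 in endothelial-like against smooth muscle-like (0), 153 between the smooth muscle-like clusters (1), 1560 for the Vwf-led (0) and 218 for the Sema3g-led endothelial-like cluster (0). Classes and clusters were formed from the same counts, so the real split calls more genes by construction and is no evidence for the grouping.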
